A study of Mus musculus with 39 samples.

How the data were processed

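Intestinal contents of mice were profiled in 24 metagenomic shotgun libraries and 15 libraries of the 16S rRNA gene. Per the labels' protocols, microbial DNA was extracted and made into whole-genome shotgun libraries for the first assay. For the second, per the labels' protocols, nucleic acids were taken up with a magnetic-bead kit and a region spanning nearly the whole 16S rRNA gene was amplified. The authors deposited 1 table per assay in which each value is a fraction of the library, from 0 to 1, with each column summing to 1. The classifier, reference database, removal of host reads, denoising and filters behind these fractions are not given in the sources used here. They can affect the values, since a share depends on which reads were assigned and on every other share in the library. Depth is not given, and no counts were inferred from the decimals. In every library 100% of the values were whole multiples of a step, the smallest non-zero value in 16S and a fraction of it in the metagenome. Such steps would give a depth only if the reads behind a step were known. The smallest non-zero value of a library was 4.53e-05% to 0.000392% in the metagenome table and 0.00176% to 0.00314% in the 16S table. No column belonged to another series (0 columns), and no 2 columns of a table were identical.

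Groups and replicate numbers were taken from the sample titles. The titles do not say that a replicate number marks a shared animal, donor or cage, and the numbers were not used to pair libraries. The library names of the aged groups put the letters AA on opposite groups: AA marks Aged+AF in 16S and Aged+YF in the metagenome, where Aged+AF has CC. The titles were followed. If the aged metagenome groups were exchanged, every metagenome difference between them would change sign, and the comparisons of each with Young+YF would change places. Whether both assays used the same animals is not given in the sources used here. The metagenome table gives names without lineages, so the first word of a name was taken as its genus. The 16S name Unassigned, above 0 in 2 libraries and at most 0.0112%, was left out.

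Names above 0 in at least 4 metagenome libraries (4813 names) or 3 16S libraries (311 names) were tested with limma 3.58.1 in R 4.3.3 on log2(share + 0.5 times the smallest non-zero share of the table), a constant of 2.26e-05% in the metagenome and 0.000880% in 16S. The fit held the 3 groups of an assay, with trended empirical Bayes variances and Benjamini-Hochberg adjustment within each comparison at 0.05. The log2 differences are on that scale, and those of rare names depend on the added constant. A count of libraries on one side means libraries of the first group on the called side of the second group's mean log2 share. Where the design written beforehand named a test for counts, the one for relative abundances was used, as the tables hold no counts. Communities were compared with PERMANOVA on Bray-Curtis distances, with 99999 permutations over 3 groups and all splits for each pair. Position, Shannon diversity and summed lists were compared with two-sided exact permutation tests, and lists were adjusted over the lists of an assay within a comparison. Changes of 182 shared genera were compared between assays by rank correlation with 1000 permutations of the 16S labels and by a limma interaction of assay and group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

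The tests, the alternatives, the lists of genera and the rule for naming taxa were fixed before the data were examined. Taxa named are, per assay and comparison, up to 10 in each direction with the largest difference among those past the test and at least 0.1% in either group, the 5 most abundant, and up to 4 of the most abundant members of each list. Phyla and functional lists in the rule could not be used because the tables give neither. Lists of fungi and of mouse retroviruses were added after the data were examined. Alternatives covered scaling, filters, the added constant, an exact rank-sum test, genus level, a replicate block, fits of 2 groups, other distances and indices, and leaving out each library. Leaving out the 7 libraries low in Blautia sp.YL58, leaving out fungi, viruses and associated names, and testing only names of at least 0.1% were added later.

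The limma step was tested on simulated data in which 200 metagenome names were changed. It recovered 46%, 44% and 33% of log2 changes of 4 in Aged+AF against Young+YF, Aged+YF against Aged+AF and Aged+YF against Young+YF (4806, 4807 and 4808 names tested), and 1%, 2% and 1% of log2 changes of 2. With 30 changed 16S genera it recovered 0%, 0% and 33.3% of log2 changes of 4 in the same order (299, 281 and 286 genera), and 0% of log2 changes of 2 in each. A 16S genus or a metagenome name that missed the test can therefore not be taken as unchanged. Other numbers of libraries were not simulated. The permutation step was simulated with groups of 8. It found 100% of shifts of 3 SD, with 6.5% false calls. It also found 100% of simulated communities in which 10 of 60 names were raised 6-fold, with 2% false calls. Smaller shifts, groups of 5 and communities as large as the real ones were not simulated. The interaction step recovered 90% of 20 genera changed by a log2 of 5 among 182 in Aged+AF against Young+YF, with 2 false calls.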

Results

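Microbial DNA was measured in the intestinal contents of mice from 3 groups, named Young+YF, Aged+AF and Aged+YF in the labels. The series concerns faecal transplantation between animals of different reproductive age. The first word of each name was read as the age of the recipient, and the letters YF and AF are not spelled out in the labels. Metagenomic shotgun libraries numbered 24, with 8 in each group, and libraries of the near full-length 16S rRNA gene numbered 15, with 5 in each group. The metagenome table listed 5589 species-level names, with between 2129 and 4267 above 0 in a library. The 16S table listed 673 genus-level names, with between 125 and 242 above 0 in a library. All values were shares of a library, the depth behind them was not given, and no counting interval was computed. The labels do not say that the libraries came from separate animals, and the p-values measure the spread between these libraries, which may be technical.

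The most abundant metagenome species were Blautia sp.YL58, Parabacteroides distasonis, [Clostridium] innocuum, Bacteroides caecimuris and Curtobacterium flaccumfaciens. Blautia sp.YL58, a strict anaerobe cultured from the mouse gut, made up 10.8% ± 5.01 of Young+YF, 5.58% ± 6.45 of Aged+AF and 9.42% ± 8.27 of Aged+YF libraries (SD, n = 8 each). It was below 1% in 7 libraries, which were Young+YF replicate 4, Aged+AF replicates 1, 2 and 4, and Aged+YF replicates 4, 5 and 7. Those 7 libraries listed between 3385 and 4267 names and had Shannon indices of 4.03 to 4.37, against 2129 to 3330 names and indices of 2.68 to 3.38 in the other 17. They held 1 library of Young+YF and 3 of each aged group. Parabacteroides distasonis averaged 11.8%, 5.55% and 7.19% in Young+YF, Aged+AF and Aged+YF, and [Clostridium] innocuum averaged 9.10%, 4.48% and 5.90%. Curtobacterium flaccumfaciens, a species better known from plants, averaged 2.13%, 5.19% and 9.41%. None of these 4 species passed limma between any pair of groups. The limma adjusted p was at least 0.427 for Blautia sp.YL58, 0.525 for Parabacteroides distasonis, 0.611 for [Clostridium] innocuum and 0.456 for Curtobacterium flaccumfaciens. A miss does not show that a species was unchanged.

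The comparison of Aged+AF with Young+YF asked how the gut community of the aged group under AF differed from that of the young group under YF. Age and material differ together between these groups, and no young group under AF was labelled. A difference here can therefore not be assigned to age or to material. Flavonifractor plautii, an anaerobe that breaks down flavonoids, rose from 0.605% ± 0.599 in Young+YF to 3.67% ± 1.90 in Aged+AF (SD, n = 8 each). Akkermansia muciniphila, which feeds on intestinal mucin, fell from 6.27% ± 4.53 to 0.822% ± 1.44. Alistipes finegoldii, a bile-tolerant member of the Rikenellaceae, fell from 0.129% ± 0.0316 to 0.04995% ± 0.0646. Staphylococcus aureus rose from 0.0162% ± 0.0310 to 0.103% ± 0.0951, and among the Enterobacterales Citrobacter sp.RHB35-C17 fell from 0.113% ± 0.182 to 0.00171% ± 0.00485. These were the 5 species that passed the test among the 74 with a mean share of at least 0.1% in either group.

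On the log2 scale limma gave differences of 3.94 for Flavonifractor plautii (adjusted p = 0.0143) and 3.16 for Staphylococcus aureus (adjusted p = 0.0187), and 8 of 8 Aged+AF libraries lay above the Young+YF mean for each. The limma differences were -4.68 for Akkermansia muciniphila (adjusted p = 0.0299), -2.12 for Alistipes finegoldii (adjusted p = 0.0164) and -8.68 for Citrobacter sp.RHB35-C17 (adjusted p = 0.000248). Of the 8 Aged+AF libraries, 7 lay below the Young+YF mean for Akkermansia muciniphila and for Alistipes finegoldii, and 8 for Citrobacter sp.RHB35-C17. The limma difference of Akkermansia muciniphila was -4.62 to -3.95 (adjusted p = 0.0504 to 0.0759) when Young+YF replicate 1, 2, 3, 5 or 6 or Aged+AF replicate 1, 2 or 5 was left out, and -4.11 (adjusted p = 0.148) without the 7 libraries low in Blautia sp.YL58. Citrobacter sp.RHB35-C17 was above 0 in 7 of 8 Young+YF and 1 of 8 Aged+AF libraries, so the size of its log2 difference depends on the small constant added to each share.

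**Figure D1:**
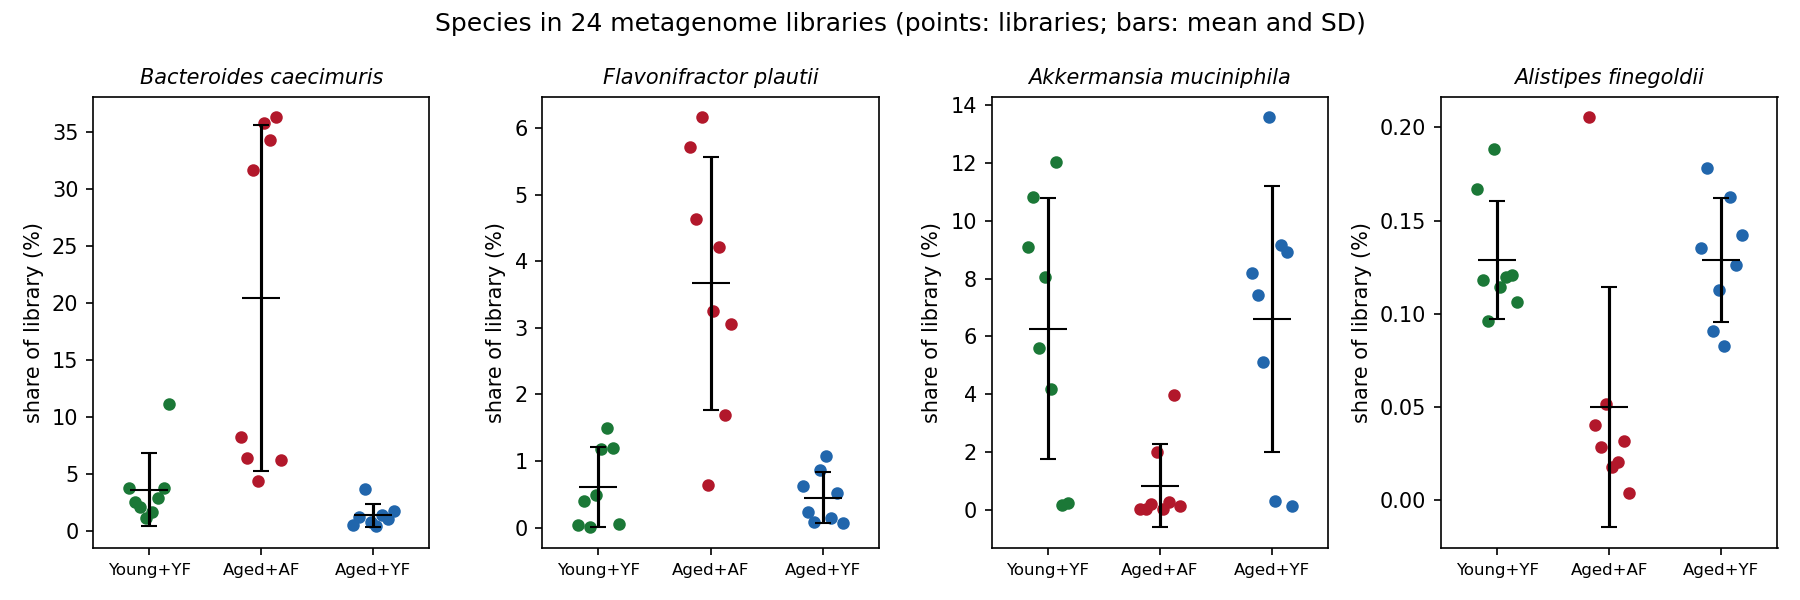
Share of the library, in percent, for Bacteroides caecimuris, Flavonifractor plautii, Akkermansia muciniphila and Alistipes finegoldii in 24 metagenome libraries. Points are libraries, and the black bars are the mean and SD of each group (n = 8). Flavonifractor plautii averaged 3.67% in Aged+AF against 0.605% in Young+YF (limma adjusted p = 0.0143) and 0.452% in Aged+YF (limma adjusted p = 0.0512).

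Among the groups of taxa fixed beforehand, the Oscillospiraceae and Ruminococcaceae together rose from 0.946% ± 1.03 in Young+YF to 4.601% ± 2.58 in Aged+AF (SD, n = 8 each). The log2 difference was 3.41, 8 of 8 Aged+AF libraries lay above the Young+YF mean, and the two-sided exact permutation test gave an adjusted p of 0.0112 over 18 lists. Of its 11 tested members, 1 rose, Flavonifractor plautii, and the count adjusted over the list alone was also 1. That species, described above, made up most of the rise in mean share. Acutalibacter muris, at 0.217% and 0.552%, and Flintibacter sp.KGMB00164, at 0.0257% and 0.166%, did not pass. Acutalibacter muris passed in limma without the 7 libraries low in Blautia sp.YL58 (1.63, adjusted p = 0.00619), and Flintibacter sp.KGMB00164 without Young+YF replicate 4 (5.22, adjusted p = 0.0464). Without Aged+AF replicate 2, 3, 5, 6 or 8 the difference of the list stayed at 3.30 to 3.46 with exact adjusted p of 0.0503 to 0.0643, and it was 3.64 (exact adjusted p = 0.0909) without the 7 libraries low in Blautia sp.YL58. The Rikenellaceae list stood at 0.663% ± 0.265 in Young+YF and 0.323% ± 0.278 in Aged+AF, with an exact adjusted p of 0.0550. Of its 8 members 3 fell, and 5 fell when adjusted over the list alone. The Rikenellaceae total passed without Young+YF replicate 8 (exact adjusted p = 0.0483) or Aged+AF replicate 1 or 4 (exact adjusted p = 0.0252 and 0.0336). It also passed with centred log-ratios (-1.90, exact adjusted p = 0.00280) and without the 7 libraries low in Blautia sp.YL58 (-1.91, exact adjusted p = 0.0227). The Akkermansia total, nearly all of it Akkermansia muciniphila, differed by -4.66 (exact adjusted p = 0.0550). Of its 2 members 1 fell, over all names and adjusted over the list alone. The Akkermansia total passed without Young+YF replicate 8 (exact adjusted p = 0.0483) or Aged+AF replicate 4 or 7 (exact adjusted p = 0.0457 and 0.0364), and with centred log-ratios (-5.19, exact adjusted p = 0.0308). Among 123 facultative Gram-positive cocci 7 rose, Staphylococcus aureus among them, and 1 fell, with the same counts adjusted over the list alone. Over all 4813 names limma called 233 higher and 93 lower, and the share of cocci that rose was close to that. Among 101 Enterobacterales 1 rose and 5 fell, and 3 rose and 6 fell when adjusted over the list alone. Klebsiella pneumoniae averaged 0.417% in Young+YF and 0.0116% in Aged+AF and did not pass (limma difference -3.31, adjusted p = 0.0737). It passed in limma with centred log-ratios (-3.90, adjusted p = 0.0419), with median-ratio scaling (-3.98, adjusted p = 0.0236) and with the 2 groups alone (adjusted p = 0.0475). It also passed in limma without Young+YF replicate 1 or 4 or Aged+YF replicate 3 (adjusted p = 0.0397, 0.0445 and 0.0486).

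A few more named species missed the test between Aged+AF and Young+YF with all libraries and passed under other settings. Bacteroides caecimuris stood at 20.4% ± 15.2 in Aged+AF and 3.63% ± 3.18 in Young+YF (limma difference 2.34, adjusted p = 0.123). It passed in limma among names of at least 0.01% (adjusted p = 0.0267) or at least 0.1% (adjusted p = 0.0170), and without the 7 libraries low in Blautia sp.YL58 (2.90, adjusted p = 0.0477). Alistipes shahii stood at 0.0693% and 0.160% and passed in limma with centred log-ratios (-2.45, adjusted p = 0.00316), with median-ratio scaling (-2.53, adjusted p = 0.00181) and without those 7 libraries (-2.72, adjusted p = 0.00347). It also passed in limma without Aged+AF replicate 1 or 4 (adjusted p = 0.0402 and 0.0306). Duncaniella dubosii, at 1.66% and 6.81%, passed in limma without those 7 libraries (-3.57, adjusted p = 0.0303), and Helicobacter typhlonius, at 0.0923% and 0.0308%, without Young+YF replicate 8 (4.57, adjusted p = 0.0306).

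Over all 4813 names tested, limma called 326 between Aged+AF and Young+YF, of which 233 were higher and 93 lower in Aged+AF, and 965 had an unadjusted p under 0.05. Most of these names were rare, as the 5 species at or above 0.1% show. The median log2 difference of all names was 0.58, and it was -0.01 after centred log-ratio scaling, which called 271 names higher and 274 lower. Median-ratio scaling called 333 higher and 292 lower, and limma without the 7 libraries low in Blautia sp.YL58 called 613 names, 277 of them among the 326.

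The comparison of Aged+YF with Aged+AF asked what differed between aged groups given different material. Bacteroides caecimuris, first isolated from mouse caecum, fell from 20.4% ± 15.2 in Aged+AF to 1.37% ± 1.05 in Aged+YF (SD, n = 8 each), and its Young+YF mean was 3.63% ± 3.18. Akkermansia muciniphila rose from 0.822% ± 1.44 to 6.60% ± 4.6004. Helicobacter hepaticus, a common colonist of the mouse caecum and colon, fell from 0.320% ± 0.562 to 0.00270% ± 0.00640, and Helicobacter typhlonius was above 0 in 8 of 8 Aged+AF libraries and listed at 0 in 8 of 8 Aged+YF libraries. Alistipes finegoldii rose from 0.04995% ± 0.0646 to 0.129% ± 0.0331, and Alistipes shahii from 0.0693% ± 0.0780 to 0.216% ± 0.141. Bacteroides cellulosilyticus, which degrades plant cell-wall sugars, fell from 0.600% ± 0.601 to 0.0746% ± 0.111, and Bacteroides sp.CBA7301 fell from 1.90% ± 1.72 to 0.294% ± 0.368.

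The limma differences were -3.72 for Bacteroides caecimuris (adjusted p = 0.0119), -3.50 for Bacteroides cellulosilyticus (adjusted p = 0.0130), -3.06 for Bacteroides sp.CBA7301 (adjusted p = 0.0232) and -8.48 for Helicobacter hepaticus (adjusted p = 0.00536), each lower than the Aged+AF mean in 8 of 8 Aged+YF libraries. For Helicobacter typhlonius the limma adjusted p was 0.00185. The limma differences were 4.76 for Akkermansia muciniphila (adjusted p = 0.0344, higher in 7 of 8), 2.11 for Alistipes finegoldii (adjusted p = 0.0239, higher in 8 of 8) and 2.20 for Alistipes shahii (adjusted p = 0.0419, higher in 8 of 8). These 7 species at or above 0.1%, Helicobacter typhlonius aside, were the ones past the test among 83.

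Several of these calls missed the threshold under other settings. For Bacteroides caecimuris limma gave -3.66 (adjusted p = 0.0559) after centred log-ratio and -3.69 (adjusted p = 0.0513) after median-ratio scaling, and leaving out 1 library never ended its call. Akkermansia muciniphila differed by 4.02 to 4.79 (limma adjusted p = 0.0503 to 0.0832) without Aged+AF replicate 1, 2, 5 or 8 or Aged+YF replicate 1, 2, 3, 4, 6 or 7, by 4.76 (adjusted p = 0.0646) in a limma fit of the 2 aged groups alone, and by 4.36 (adjusted p = 0.128) without the 7 libraries low in Blautia sp.YL58. For Alistipes finegoldii limma gave 1.68 (adjusted p = 0.0544) without Aged+AF replicate 8, and an unchanged 2.11 (adjusted p = 0.0818) with the 2 aged groups alone. For Alistipes shahii it gave 1.83 to 2.30 (adjusted p = 0.0501 to 0.0962) without Young+YF replicate 3 or 5, Aged+AF replicate 3, 5, 6, 7 or 8, or Aged+YF replicate 2, 4, 6, 7 or 8, and an unchanged 2.20 with the 2 aged groups alone (adjusted p = 0.106) and with replicate number as a block (adjusted p = 0.0516). Bacteroides sp.CBA7301 differed by -1.68 without the 7 libraries low in Blautia sp.YL58 (limma adjusted p = 0.168) and had a limma adjusted p of 0.0729 with the 2 aged groups alone. Bacteroides cellulosilyticus differed by -3.79 without those 7 libraries, more than with them, at a limma adjusted p of 0.0542.

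Flavonifractor plautii, at 3.67% ± 1.90 in Aged+AF and 0.452% ± 0.380 in Aged+YF, missed the test between these groups (limma difference -3.37, adjusted p = 0.0512). It passed in limma with centred log-ratios (-3.31, adjusted p = 0.0356), with median-ratio scaling (-3.34, adjusted p = 0.0349), with the 2 aged groups alone (adjusted p = 0.0348), with a 10th of the added constant (adjusted p = 0.0409) and without the 7 libraries low in Blautia sp.YL58 (-4.36, adjusted p = 0.0494). With replicate number as a block the limma adjusted p was 0.0485, and among names of at least 0.01% or 0.1% it was 0.0365 and 0.0251. Without Young+YF replicate 3, 4, 6 or 7, Aged+AF replicate 4, or Aged+YF replicate 4, 5 or 7 the limma difference was -3.69 to -3.37 (adjusted p = 0.0219 to 0.0497). Acutalibacter muris passed in limma without the 7 libraries low in Blautia sp.YL58 (-1.45, adjusted p = 0.0198).

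By group of taxa, Bacteroides and relatives fell from 44.9% ± 16.8 of Aged+AF to 20.1% ± 11.7 of Aged+YF libraries (log2 difference -1.45, lower in 8 of 8, exact adjusted p = 0.0231). Of 27 members 5 fell, and 8 fell when adjusted over the list alone. Bacteroides caecimuris, a member described above, made up most of the fall in mean share. Phocaeicola vulgatus, at 5.21% and 1.44%, and Bacteroides thetaiotaomicron, at 3.72% and 2.08%, did not pass. The Rikenellaceae rose from 0.323% ± 0.278 to 0.742% ± 0.244 (log2 difference 1.54, higher in 8 of 8, exact adjusted p = 0.0231), with 5 of 8 members higher, and 6 when adjusted over the list alone. The Helicobacteraceae fell from 0.472% ± 0.667 to 0.0122% ± 0.0150 (log2 difference -3.96, lower in 8 of 8, exact adjusted p = 0.0231), with 4 of 15 members lower, and 7 when adjusted over the list alone. The list of Lachnospiraceae of the mouse gut, which leaves out Blautia, rose from 2.94% ± 2.10 to 7.71% ± 4.37 (log2 difference 1.53, higher in 8 of 8, exact adjusted p = 0.0231). Of its 6 members 0 passed limma, either over all names or adjusted over the list alone. Among them Enterocloster bolteae averaged 1.36% and 5.31%. The Akkermansia list rose from 0.822% ± 1.44 to 6.60% ± 4.6006 (log2 difference 4.73, higher in 7 of 8, exact adjusted p = 0.0319), with 1 of 2 members higher, and 2 when adjusted over the list alone. Nearly all of that list is Akkermansia muciniphila, so its total restates that species.

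All 5 of these totals missed the threshold without Aged+AF replicate 3 or 5 or Aged+YF replicate 1 or 6, with exact adjusted p of 0.0513 to 0.0716. All 5 also missed it with replicate number as a block (exact adjusted p = 0.0844 each). The Akkermansia total also missed it without Aged+AF replicate 1, 2 or 8 or Aged+YF replicate 2, 3, 4 or 7, at 0.0543 to 0.0688. After centred log-ratio scaling the Bacteroides and relatives total differed by -1.42 with an exact adjusted p of 0.311. Without the 7 libraries low in Blautia sp.YL58 that total differed by -0.91 (exact adjusted p = 0.0952), and the Akkermansia total by 4.35 (exact adjusted p = 0.179). The Oscillospiraceae and Ruminococcaceae stood at 2.09% ± 2.86 in Aged+YF against 4.601% ± 2.58 in Aged+AF (exact adjusted p = 0.0592), and passed without Aged+YF replicate 4, 5 or 7, at 0.0414, 0.0319 and 0.0369. It also passed with centred log-ratios (-2.57, exact adjusted p = 0.0168) and without the 7 libraries low in Blautia sp.YL58 (-4.10, exact adjusted p = 0.0357).

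Over all names, limma called 227 between Aged+YF and Aged+AF, 88 higher and 139 lower in Aged+YF, with 844 at an unadjusted p under 0.05. An exact rank-sum test called 30, a limma fit of the 2 aged groups alone called 101, and limma without the 7 libraries low in Blautia sp.YL58 called 803. Of the names called in both comparisons that involve Aged+AF, 96 were higher in Aged+AF than in both other groups and 53 lower, 149 in all. Both comparisons share the Aged+AF libraries. Simulated unchanged groups gave a median of 0 and at most 9 such names, independent lists of these sizes would share 8.43, and splitting the Aged+AF libraries between the comparisons gave 49 and 54. Such a split does not remove a technical effect common to all Aged+AF libraries, for which names listed only in that group are described below. The log2 differences of the comparisons had a correlation of -0.719 across names, against -0.541 in the simulation, and a covariance of -1.29 against -0.269.

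The comparison of Aged+YF with Young+YF asked what remained different between aged and young groups under YF. Citrobacter sp.RHB35-C17 fell from 0.113% ± 0.182 in Young+YF (above 0 in 7 of 8 libraries) to 0.000104% ± 0.000295 in Aged+YF (above 0 in 1 of 8). The limma difference was -9.18 (adjusted p = 0.00224, lower in 8 of 8), and with the 2 groups alone the limma adjusted p was 0.0633. The other names past the test lay under 0.1% and were chosen for mention after their values were seen. Citrobacter sp.Y3 was above 0 in 6 of 8 Young+YF libraries (mean 0.0130%) and listed at 0 in 8 of 8 Aged+YF libraries (limma adjusted p = 0.00605). Candidatus Arthromitus sp.SFB-mouse, the segmented filamentous bacterium that attaches to the ileal epithelium, was above 0 in 6 of 8 Young+YF libraries (mean 0.00739%) and 1 of 8 Aged+YF libraries (limma adjusted p = 0.0337). Candidatus Arthromitus sp.SFB-mouse-NL was above 0 in 6 of 8 Young+YF libraries (mean 0.00466%) and listed at 0 in 8 of 8 Aged+YF libraries (limma adjusted p = 0.0337).

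These 4 names, all lower in Aged+YF, were the calls of limma out of 4813, with 488 at an unadjusted p under 0.05, and the exact rank-sum test called 0. Limma called 2 without Young+YF replicate 1, 3, 4, 5 or 7 or Aged+YF replicate 3, 5 or 7, called 9 without Aged+YF replicate 2 and 7 without Aged+YF replicate 6, and called 16 without the 7 libraries low in Blautia sp.YL58. Centred log-ratio scaling called 12 higher and 40 lower, and median-ratio scaling 19 higher and 44 lower, where the median log2 difference of all names was 0.62 on the scale of shares and 0.09 and 0.15 under these scalings. Of the 18 lists 0 passed the exact test between these groups. The Lachnospiraceae of the mouse gut stood at 7.71% ± 4.37 in Aged+YF and 3.04% ± 3.33 in Young+YF (exact adjusted p = 0.161), and the facultative Gram-positive cocci at 0.874% ± 0.814 and 0.286% ± 0.165 (exact adjusted p = 0.161). The cocci passed with centred log-ratios (0.78, exact adjusted p = 0.0168). Among them Staphylococcus aureus stood at 0.129% and 0.0162%, and it passed in limma with centred log-ratios (2.32, adjusted p = 0.0170) and with median-ratio scaling (2.22, adjusted p = 0.0159), not on the scale of shares.

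The totals of the remaining metagenome groups of taxa did not pass the exact tests of shares between any pair of groups with all libraries. Values here are means ± SD in Young+YF, Aged+AF and Aged+YF, in that order (n = 8 each). Butyrate and other short-chain fatty acid producers, led by Blautia sp.YL58 and Blautia producta, made up 22.6% ± 9.09, 13.3% ± 11.2 and 20.8% ± 14.6, and 0 of 23 members passed limma in any comparison. Lactobacilli, led by Lactobacillus murinus and Lactobacillus reuteri, made up 7.59% ± 6.82, 7.16% ± 5.23 and 5.45% ± 3.94. Of 91 lactobacilli 2 fell from Aged+AF to Aged+YF, and 1 when adjusted over the list alone, which also gave 1 lower in Aged+YF than in Young+YF. Muribaculaceae, led by Duncaniella dubosii, made up 10.7% ± 6.53, 4.30% ± 4.98 and 5.78% ± 7.22, and their total fell in Aged+AF against Young+YF when Young+YF replicate 8 was left out (log2 difference -2.17, exact adjusted p = 0.0483) and with centred log-ratios (-2.28, exact adjusted p = 0.0308). Bifidobacteria stood at 0.0454% ± 0.0146, 0.0848% ± 0.0870 and 0.556% ± 1.14, and Prevotellaceae at 0.121% ± 0.192, 0.0950% ± 0.0943 and 0.0862% ± 0.0775. Desulfovibrionaceae stood at 0.303% ± 0.223, 0.373% ± 0.231 and 0.201% ± 0.174, and Erysipelotrichales at 0.142% ± 0.0638, 0.175% ± 0.180 and 0.125% ± 0.0515. Of 19 bifidobacteria 1 rose from Young+YF to Aged+AF, over all names and adjusted over the list alone. Enterobacterales totalled 0.837% ± 0.923, 0.328% ± 0.207 and 0.883% ± 0.824. Of 101 Enterobacterales 2 rose from Aged+AF to Aged+YF, 1 when adjusted over the list alone, and 2 were lower in Aged+YF than in Young+YF both ways. Of 123 facultative Gram-positive cocci 6 fell from Aged+AF to Aged+YF, both over all names and adjusted over the list alone. Corynebacterium and Brevibacterium, genera that hold industrial glutamate producers, totalled 0.00827% ± 0.0145, 0.0241% ± 0.0305 and 0.0213% ± 0.0293. Of their 62 members 2 rose and 2 fell from Young+YF to Aged+AF, and 3 rose and 2 fell when adjusted over the list alone. Genera often met as reagent or environmental DNA totalled 0.128% ± 0.0699, 0.142% ± 0.111 and 0.190% ± 0.151, with Aged+YF above Aged+AF when centred log-ratios were used (0.49, exact adjusted p = 0.0350), and virus names 0.112% ± 0.0872, 0.0863% ± 0.0615 and 0.143% ± 0.0774. Of 334 reagent and environment names 15 rose and 12 fell from Young+YF to Aged+AF, against 19 and 15 adjusted over the list alone, and 8 rose and 3 fell from Aged+AF to Aged+YF, against 7 and 2. Of 108 virus names 9 rose from Young+YF to Aged+AF, 11 when adjusted over the list alone, and 8 fell from Aged+AF to Aged+YF both ways. Whether any of these member counts exceeds the share called over all names was not tested.

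Whole metagenome communities of Aged+AF and Young+YF lay 0.564 ± 0.107 apart in Bray-Curtis distance, those of Aged+YF and Aged+AF 0.601 ± 0.132, and those of Aged+YF and Young+YF 0.494 ± 0.189. Within groups the distance was 0.398 ± 0.145 in Young+YF, 0.495 ± 0.160 in Aged+AF and 0.524 ± 0.203 in Aged+YF (SD over 28 pairs each). Group explained 24.2% of the squared distances (permutation p = 0.0032). Between Aged+AF and Young+YF it explained 25.3% (exact p = 0.000932, adjusted 0.00280), between Aged+YF and Aged+AF 19.4% (exact p = 0.0159, adjusted 0.0238), and between Aged+YF and Young+YF 12.8% (exact p = 0.0844, adjusted 0.0844). The difference between the aged groups missed the threshold without Aged+AF replicate 3, 5 or 6 or Aged+YF replicate 2 or 3 (exact adjusted p = 0.0608, 0.0769, 0.0552, 0.0524 and 0.0508), and that between the YF groups passed without Young+YF replicate 4 (exact adjusted p = 0.0399). Without the 7 libraries low in Blautia sp.YL58 all 3 pairs passed, with exact adjusted p of 0.00379, 0.0119 and 0.0139. On square-root shares neither pair with Aged+AF passed (exact adjusted p = 0.0522 and 0.101).

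Aged+YF libraries were on average 0.494 from Young+YF and 0.601 from Aged+AF, a difference of -0.108, and 7 of 8 lay closer to Young+YF. The two-sided exact permutation p was 0.000155, the smallest that exchanging the Young+YF and Aged+AF labels can give. Shannon diversity was 3.23 ± 0.387 in Young+YF, 3.42 ± 0.691 in Aged+AF and 3.51 ± 0.574 in Aged+YF (SD, n = 8 each), and no pair passed (two-sided exact adjusted p = 0.752 for each).

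**Figure D2:**
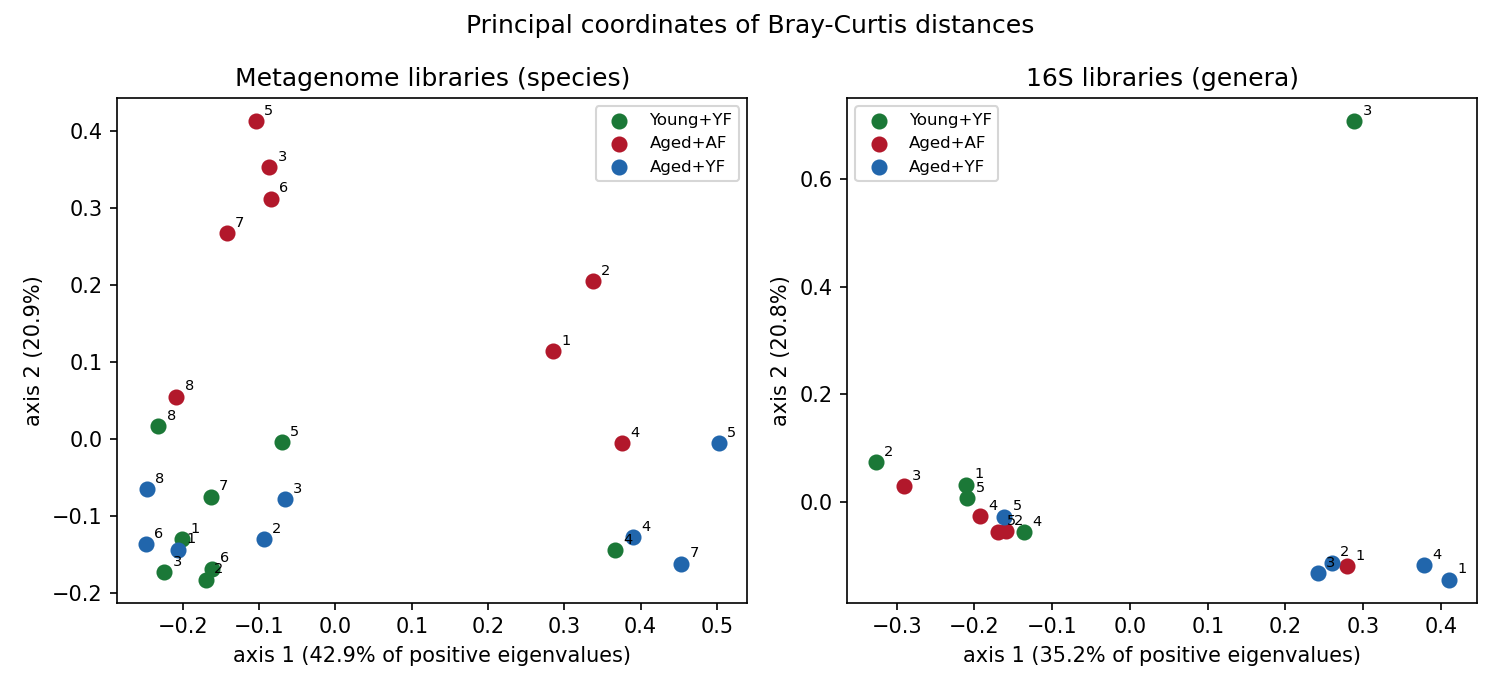
Principal coordinates of Bray-Curtis distances for 24 metagenome libraries (species) and 15 libraries of the 16S rRNA gene (genera), with each axis labelled by its share of the positive eigenvalues. Points are libraries, coloured by group and numbered by replicate. In the metagenome panel the 7 libraries low in Blautia sp.YL58 lie to the right on axis 1, which holds 42.9%.

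In the 16S libraries Lactobacillus made up 22.5% ± 13.5 of Young+YF, 24% ± 12.6 of Aged+AF and 9.97% ± 14.4 of Aged+YF (SD, n = 5 each). Limosilactobacillus made up 15.9%, 19.0% and 6.72%, Ligilactobacillus 11.9%, 10.4% and 12.1%, Odoribacter 0.481%, 11.8% and 8.32%, and the Lachnospiraceae NK4A136 group 2.66%, 5.07% and 16.8%. None of these 5 most abundant genera passed limma between groups. The lowest limma adjusted p among them was 0.267, for the Lachnospiraceae NK4A136 group in Aged+YF against Young+YF. Helicobacter fell from 14.1% ± 29.2 in Young+YF to 0.00996% ± 0.00891 in Aged+AF and was the genus limma called between these groups out of 311 (log2 difference -7.92, adjusted p = 0.00290, lower in 5 of 5). Young+YF replicate 3 alone held 66.3% Helicobacter, and without it the difference was -6.63 (exact p = 0.00794). In Aged+YF Helicobacter stood at 0.574% ± 0.473 (limma adjusted p = 0.187 against Aged+AF).

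Limma called 1 genus in Aged+AF against Young+YF, with 19 at an unadjusted p under 0.05, and the exact rank-sum test called 0. With 5 libraries a side the smallest p of the rank-sum test is 0.00794, and adjusting over 311 genera could pass it only if many genera reached it together, so its count of 0 carries little weight in the 3 comparisons. The limma count was 2 without Young+YF replicate 1 or 3 or Aged+YF replicate 2 or 3. In Aged+YF against Aged+AF limma called 0, with 24 at an unadjusted p under 0.05, and the exact rank-sum test called 0. Without Aged+YF replicate 3 limma called 3, and Roseburia, a butyrate producer at 0.0595% in Aged+AF and 4.79% in Aged+YF, was among them (limma adjusted p = 0.0154, against 0.187 with all libraries). In Aged+YF against Young+YF limma called 0, with 35 at an unadjusted p under 0.05, and the exact rank-sum test called 0. Limma called 1 without Young+YF replicate 3, Aged+AF replicate 2 or Aged+YF replicate 1. The median log2 differences of all genera were -0.13, 0.45 and 0.44 in the 3 comparisons, and 0.07, -0.11 and 0.07 after centred log-ratio scaling.

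By group of taxa, 0 of 18 16S totals passed the exact test in any comparison. The lowest exact adjusted p was 0.0714, reached by the Enterobacterales and Helicobacteraceae in Aged+AF against Young+YF and by the Rikenellaceae and Lachnospiraceae of the mouse gut in Aged+YF against Young+YF. These had the smallest exact p that 5 libraries a side can give, 0.00794, and 1 or 2 of 18 lists at that p cannot pass. Values again follow the order Young+YF, Aged+AF and Aged+YF (n = 5 each). The Lachnospiraceae of the mouse gut stood at 4.86% ± 5.31, 6.52% ± 4.94 and 22.0% ± 7.00, and 0 of 10 members passed limma over all genera, while 4 were higher in Aged+YF than in Young+YF when adjusted over the list alone. Rikenellaceae, led by Alistipes, stood at 1.75% ± 1.75, 4.66% ± 6.24 and 8.65% ± 3.43, and Enterobacterales at 0.106% ± 0.0410, 0.431% ± 0.199 and 0.378% ± 0.345. Bacteroides and relatives stood at 3.09% ± 3.75, 16.3% ± 12.8 and 13.8% ± 14.2. Lactobacilli together made up 50.3% ± 28.4, 53.4% ± 25.3 and 28.8% ± 19.0. Butyrate and other short-chain fatty acid producers, led by Roseburia, stood at 0.950% ± 0.983, 0.244% ± 0.182 and 5.31% ± 5.46, and 1 of 8 was higher in Aged+YF than in Aged+AF when adjusted over the list alone. Prevotellaceae stood at 0.141% ± 0.109, 0.0196% ± 0.0172 and 0.327% ± 0.248, and Muribaculum at 0.171% ± 0.217, 0.918% ± 0.867 and 3.45% ± 4.47. Adjusted over the list alone, 1 of 6 Prevotellaceae was lower in Aged+AF than in Young+YF and 2 were higher in Aged+YF than in Aged+AF. In the same way 1 of 3 Bacteroides and relatives and 1 of 3 Rikenellaceae were higher in Aged+AF than in Young+YF. Muribaculum and Helicobacter are each the only member of their list, so that adjustment changes nothing for them. Muribaculum in Aged+YF against Young+YF had an unadjusted limma p of 0.0345 and did not pass over all genera (adjusted p = 0.397). Helicobacter in Aged+YF against Aged+AF had an unadjusted limma p of 0.00146 and did not pass either (adjusted p = 0.187). Akkermansia stood at 2.36% ± 3.28, 0.704% ± 1.01 and 0.352% ± 0.502, and Desulfovibrionaceae at 3.78% ± 5.61, 1.48% ± 1.73 and 2.51% ± 4.08. Erysipelotrichales stood at 4.41% ± 8.16, 9.10% ± 14.0 and 4.86% ± 4.88, and Mucispirillum at 0.866% ± 0.642, 1.73% ± 2.18 and 0.407% ± 0.549. Oscillospiraceae and Ruminococcaceae stood at 1.89% ± 1.40, 0.562% ± 0.534 and 1.63% ± 1.30, and facultative Gram-positive cocci at 0.810% ± 1.01, 0.187% ± 0.0964 and 1.17% ± 1.06. Bifidobacterium stood at 0.0828% ± 0.108, 0.0388% ± 0.0439 and 0.0363% ± 0.0329. Corynebacterium and Brevibacterium together stood at 0.0480% ± 0.0773, 0.00134% ± 0.00207 and 0.00439% ± 0.00287, and reagent and environment genera at 0.186% ± 0.192, 0.0875% ± 0.0348 and 0.156% ± 0.106.

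Among whole 16S communities group explained 23.7% of the squared Bray-Curtis distances (permutation p = 0.0398). Between Aged+YF and Young+YF it explained 24.3% (exact p = 0.0238, adjusted 0.0714), between Aged+YF and Aged+AF 22.1% (exact p = 0.0794, adjusted 0.119), and between Aged+AF and Young+YF 9.70% (exact p = 0.659). The test over the 3 groups missed the threshold without Young+YF replicate 1 or 2, Aged+AF replicate 2, 3 or 4, or Aged+YF replicate 1, 2, 3 or 4 (permutation p = 0.0516 to 0.147). Without Aged+AF replicate 1 or Aged+YF replicate 5 both pairs with Aged+YF passed (exact adjusted p = 0.0357 in each case). Aged+YF libraries lay 0.698 from Young+YF and 0.597 from Aged+AF, a difference of 0.1005, and 0 of 5 lay closer to Young+YF (two-sided exact p = 0.127). Without Young+YF replicate 4 the difference was 0.132 (exact p = 0.0317). Shannon diversity was 2.16 ± 0.244 in Young+YF, 2.15 ± 0.426 in Aged+AF and 2.62 ± 0.294 in Aged+YF (n = 5 each, two-sided exact adjusted p = 0.119 for both pairs with Aged+YF).

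The same 3 groups were labelled in both assays, and 182 genera were listed in both tables. Genera were matched by name, and a name such as Lactobacillus need not cover the same species in both. Across these genera, which are not independent replicates, the log2 differences of the assays had Spearman correlations of 0.01996 for Aged+AF against Young+YF, -0.0337 for Aged+YF against Aged+AF and -0.0511 for Aged+YF against Young+YF. Permuting the 16S labels gave p of 0.775, 0.680 and 0.503, and 82, 95 and 94 genera had the same direction. Among the 15 genera of at least 0.1% in both assays the correlations were -0.529, -0.204 and 0.296 (permutation p = 0.194, 0.360 and 0.166). Of the list totals past the metagenome test, some went the opposite way in 16S. These were Oscillospiraceae and Ruminococcaceae in Aged+AF minus Young+YF (16S log2 difference -1.98), and Helicobacteraceae (5.19) and Akkermansia (-1.26) in Aged+YF minus Aged+AF. The others, all in Aged+YF minus Aged+AF, kept their direction: Bacteroides and relatives (-0.41), Rikenellaceae (2.10) and Lachnospiraceae of the mouse gut (2.52). None of these 16S totals passed the exact test. Helicobacter differed between assays: its Aged+AF minus Young+YF difference was 2.51 in the metagenome and -7.92 in 16S (limma interaction -10.43, adjusted p = 0.00144), and its Aged+YF minus Aged+AF difference was -3.96 and 5.19 (limma interaction 9.15, adjusted p = 0.00532). The metagenome difference of 2.51 did not pass on its own (exact p = 0.149, adjusted 0.334), nor did the 16S difference of 5.19 (limma adjusted p = 0.187). The 5 Aged+AF libraries of 16S held 0.00176% to 0.0232% Helicobacter, while the 8 Aged+AF metagenome libraries held 0.0103% to 1.65%.

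**Figure D3:**
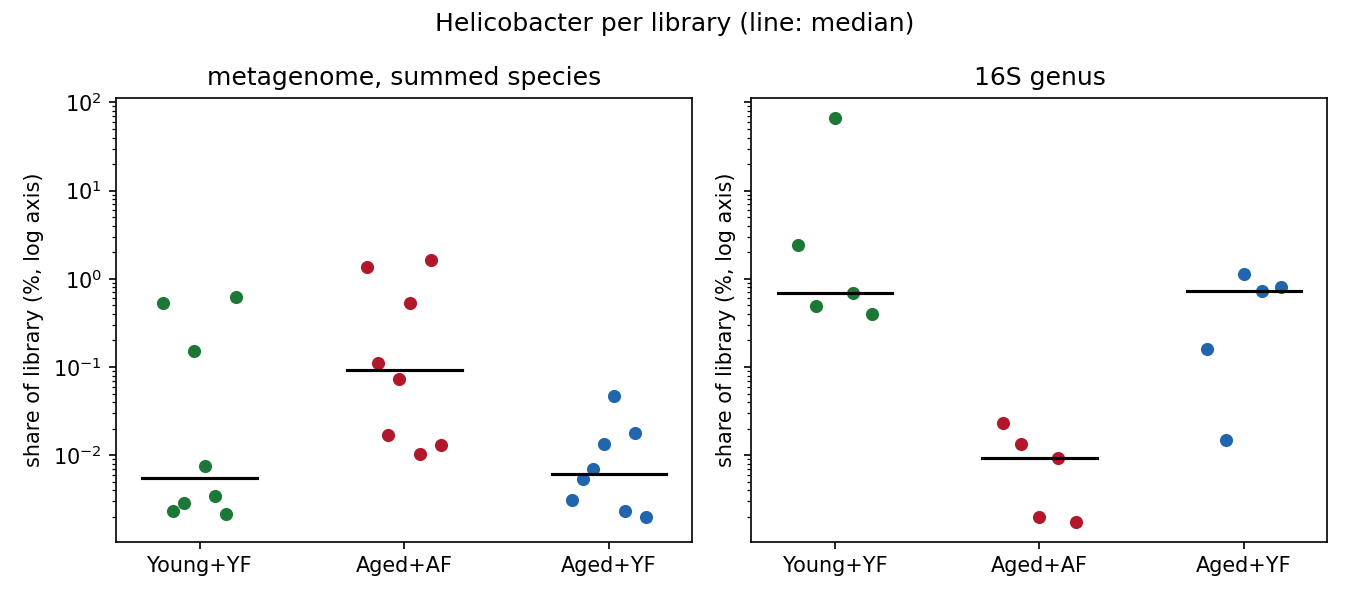
Helicobacter share of the library in percent, on a log axis, for metagenome libraries (summed species, n = 8 per group) and libraries of the 16S rRNA gene (n = 5 per group). Points are libraries and lines are group medians. In 16S, Aged+AF libraries lie between 0.00176% and 0.0232%, below every Young+YF library.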

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

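The tests of the Curtobacterium and fungal pattern, of 16S carriage of the all-or-none names and of regrouping the interaction were set down before their results were seen, while the tests of other ways to part the libraries, of depth and of a separate classification for the all-or-none names, both Helicobacter tests and the counts of splits were chosen after the results were seen.

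Of 171 groups of libraries checked for a single value far from the rest, 16 held one, and chance gives about 1 in 20. Of these, 9 involved metagenome replicate 4 of Young+YF, whose Shannon index was 4.17, butyrate producer total 3.59%, Prevotellaceae 0.591%, facultative Gram-positive cocci 0.679%, Corynebacterium and Brevibacterium total 0.0442%, Staphylococcus aureus 0.0927%, Blautia sp.YL58 0% and [Clostridium] innocuum 0.371%. Citrobacter sp.RHB35-C17 stood at 0% in that library too, at 0.0137% in Aged+AF replicate 3 and at 0.000833% in Aged+YF replicate 8, where the other libraries of those aged groups were at 0. In 16S, Young+YF replicate 3 held 1.46% lactobacilli, 0.595% Lactobacillus and 0.746% Limosilactobacillus, Aged+AF replicate 5 held 0.234% Lachnospiraceae of the mouse gut, and Young+YF replicate 1 held 0.00194% Mucispirillum. Kroppenstedtia, named after its values were seen, differed between assays as Helicobacter did. Its limma interaction was -5.09 in Aged+AF against Young+YF (adjusted p = 0.00664) and 5.67 in Aged+YF against Aged+AF (adjusted p = 0.00268), at shares of at most 0.0216% in any group.

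In the metagenome, 8 names were listed in all 8 Aged+AF libraries and in none of the other 16, and 1 name the reverse way. The first set included Hibiscus latent Fort Pierce virus, Borrelia turcica, Allofrancisella inopinata and Vibrio casei, with means from 0.000201% for Methanothrix thermoacetophila to 0.00126% for Hibiscus latent Fort Pierce virus. Choosing 8 of the 24 libraries at random gave as many such names in 1 of 100 draws, the real one, and at most 0 in the others, and lower depth is argued against by the 8 names gained. Higher depth of the Aged+AF libraries was not tested. A separate classification run or reference table for the Aged+AF libraries is a candidate explanation: these names followed mouse retrovirus names over the 8 Aged+AF libraries (Spearman rho 0.905, exact p = 0.00456, adjusted 0.00639 over 7 relations, Pearson r 0.880 with exact p = 0.00489, and 0.873 without the 2 farthest libraries), and 15 of the 16 other libraries held more retrovirus than the lowest Aged+AF library. That none of those 15 libraries lists the names was fixed by how the names were chosen. The correlation pooled Aged+AF libraries low in Blautia sp.YL58 with the others, and it was not computed within either kind. A separate run would coincide with the group, so the labels cannot part it from a difference between the animals. All 9 names were among the 326 that limma called between Aged+AF and Young+YF. The way these names were chosen favours such a call, so the calls add no evidence. More loosely, 31 names were in all 8 Aged+AF libraries and at most 3 of the 16 others, and 11 in none of the 8 and at least 13 of the others. How many of the 326 calls, or of the 149 names called in both comparisons, such a run could account for was not tested. Carriage in the animals stays open, since only 2 of the 9 genera appear in any 16S library, too few to decide, though both were listed at least as often in another 16S group.

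Curtobacterium flaccumfaciens and fungal names rose and fell together across metagenome libraries, from 0.450% to 19.8% and from 0.381% to 8.88%. A resident population stays open. Curtobacterium reached at most 0.00280% of a 16S library, under the bound set before the result was seen, but that bound was wrong: Flavonifractor averaged 1.58% of the metagenome and 0.004597% of 16S, and Blautia 18.02% and 0.127%, so a low 16S share does not mark a genus as absent. The same animals are not stated to have been used either. Mouse DNA assigned to these names may account for the pattern, as the lowest of 4 Spearman correlations with mouse retrovirus names was 0.857. Among the 17 libraries not low in Blautia sp.YL58 rho was 0.988 for fungi and 0.919 for Curtobacterium flaccumfaciens (Pearson r 0.994 and 0.918, 0.991 and 0.868 without the 2 farthest, permutation p = 1e-05 each, the smallest possible, adjusted 2.33e-05 over 7 relations). Among the other 7 rho was 1 (exact p = 0.000397, adjusted 0.000694, Pearson r 0.993 and 0.970) and 0.857 (exact p = 0.0238, adjusted 0.0238, Pearson r 0.781 with exact p = 0.0343), and the last rests on the 2 farthest libraries, without which r was 0.431.

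Helicobacter changed differently in the assays from Young+YF to Aged+AF, with a limma interaction of -10.43 (adjusted p = 0.00144). The interaction in Aged+YF against Aged+AF was 9.15 (adjusted p = 0.00532), but the 16S difference there did not pass limma (adjusted p = 0.187), and the metagenome difference of 2.51 in Aged+AF against Young+YF did not pass the exact test (adjusted p = 0.334). For Aged+AF against Young+YF, a single 16S library with a very high share is argued against, since the 16S difference was -6.63 without it and -7.92 with it. An exchange of the aged metagenome groups, which would bear on every metagenome comparison here and not on Helicobacter alone, cannot be told apart from the labels as given: the correlation of genus changes in Aged+AF against Young+YF was -0.123 with the groups exchanged and 0.01996 as labelled (permutation p = 0.179 and 0.775), and it was -0.529 as labelled among 15 abundant genera (permutation p = 0.194), so the correlations decide nothing. Differences between the animals of the assays were not tested.

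For the 326 names in Aged+AF against Young+YF, 1 of 100 splits, the real one, gave as many (highest other 11). For the 227 in Aged+YF against Aged+AF it was also 1 of 100, but the highest other split called 109. Chance is unlikely for both counts. Only 100 of 6435 possible splits were drawn, so 1 of 100 is the smallest share they can give. For the 4 names in Aged+YF against Young+YF, 4 of 100 splits gave as many, but the highest other called 356, which points to a structure of the samples. In 16S chance could not be excluded for 1 genus in Aged+AF against Young+YF (6 of 100, highest other 1). Every split reaches a count of 0, so the splits say nothing on the 0 genera in Aged+YF against Aged+AF (100 of 100, highest other 5) and in Aged+YF against Young+YF (100 of 100, highest other 18). For the 2 interaction calls in Aged+AF against Young+YF 3 of 100 regroupings, the real one included, gave as many (highest other 2). That lies just under the bound of 5 of 100, so chance is less likely there but not excluded. The 2 calls in Aged+YF against Aged+AF reached that bound (5 of 100, highest other 6). The 0 in Aged+YF against Young+YF is again reached by every regrouping (100 of 100, highest other 9), with 23 genera at an unadjusted p under 0.05 in limma.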

How the results depend on the processing

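Leaving out the libraries low in Blautia sp.YL58, leaving out fungi, viruses and associated names, and testing only names of at least 0.1% were chosen after the data were seen. Among the main results, 620 of the values under alternatives were counted as unchanged, 62 counts moved, 17 values fell short of the threshold and 9 passed it. Unchanged means a count near the main one, or a test on the same side of the threshold. A change of sign between values that both missed the threshold was counted as unchanged, as in some Shannon differences below. Among single taxa and lists 13977 were unchanged in this sense, 118 fell short, 124 passed and 1 reversed. The cause was not tested for the changes below, except that fewer names or libraries were tested under the filters, the genus level and the left-out libraries.

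In Aged+AF against Young+YF, Aged+YF against Aged+AF and Aged+YF against Young+YF, the metagenome limma counts of 326, 227 and 4 became 545, 553 and 52 with centred log-ratios, 625, 546 and 63 with median-ratio scaling, 10, 15 and 1 for names of at least 0.01%, 4, 9 and 0 for at least 0.1%, 91, 47 and 0 for genera, and 613, 803 and 16 without the libraries low in Blautia sp.YL58. The exact rank-sum test gave 30 and 0, and fits of 2 groups 101 and 0, in the comparisons with Aged+YF. Leaving out 1 library gave 246 to 473, 164 to 310 and 2 to 9. The 16S counts of 1, 0 and 0 became 2 and 1 with median-ratio scaling in the comparisons with Young+YF, and 3 and 1 with a 10th of the constant in those with Aged+AF. The rank-sum test gave 0. Leaving out 1 library gave 1 to 2, 0 to 3 and 0 to 1. Streptococcus pasteurianus in Aged+YF against Aged+AF reversed from -0.05 to 0.99 (limma adjusted p = 0.0125) without the libraries low in Blautia sp.YL58.

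As R2, metagenome communities on square roots gave 0.203 (exact adjusted p = 0.0522) for Aged+AF and Young+YF and 0.137 (0.101) for Aged+YF and Aged+AF, and without the libraries low in Blautia sp.YL58 Aged+YF and Young+YF gave 0.186 (0.0139). In 16S the Jaccard distance gave 0.167 (permutation p = 0.104) over 3 groups, and square roots gave 0.199 (exact adjusted p = 0.0476) for Aged+YF and Young+YF. Leaving out 1 library gave metagenome R2 of 0.222 to 0.285 over 3 groups, and 0.229 to 0.316, 0.169 to 0.233 and 0.0943 to 0.190 by pair, and 16S R2 of 0.201 to 0.301, 0.0849 to 0.123, 0.174 to 0.339 and 0.208 to 0.352. Position ranged from -0.135 to -0.0915 in the metagenome and 0.0516 to 0.132 in 16S. Shannon differences ranged from 0.0539 to 0.324, -0.0348 to 0.223 and 0.155 to 0.411 in the metagenome and -0.146 to 0.103, 0.361 to 0.611 and 0.366 to 0.549 in 16S. List totals past the test numbered 4 in Aged+AF against Young+YF and 1 in Aged+YF against Young+YF with centred log-ratios, and 0 to 4 and 0 to 6 in the comparisons with Aged+AF when 1 library was left out.

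Replicate numbers did not pair the libraries: 0 of 24 metagenome pairs and 3 of 15 16S pairs correlated best with their own number. With replicate number as a block the metagenome limma counts were 289, 204 and 4, list totals past the test were 0 and 0 in the comparisons with Aged+AF, and Aged+YF and Young+YF communities gave 0.128 (exact p = 0.0156). Centred log-ratios left the correlations between assays exactly as they were, since a constant shift keeps ranks, so that setting tests nothing. Thinning to equal depth and the alternatives for counts were not run, as the tables hold fractions and no counts were inferred from them. The 16S table was already at genus level. Unknown depth limits all statements on rare names.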

Other observations

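The values in this part were chosen after the data were seen, and no explanation was tested for them. The assays listed different leading genera. Over all libraries Bacteroides averaged 18.7% ± 14.6 of the metagenome (SD, n = 24) and 3.31% ± 2.57 of 16S (SD, n = 15), and Blautia averaged 18.02% ± 12.95 and 0.127% ± 0.137. Limosilactobacillus averaged 0.00399% ± 0.00473 and 13.9% ± 11.9, and Ligilactobacillus 0.00848% ± 0.0137 and 11.5% ± 11.6. Lactobacillus, the genus from which both were split, averaged 6.72% ± 5.29 and 18.8% ± 14.1. The leading metagenome lactobacilli were listed as Lactobacillus murinus and Lactobacillus reuteri, so these genus names need not cover the same species in the assays. Odoribacter averaged 0.0650% ± 0.0670 and 6.87% ± 11.4, and Turicibacter 0.0114% ± 0.0303 and 3.11% ± 6.85.

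Bifidobacterium pseudolongum, a bifidobacterium of animal guts, averaged 0.00564% ± 0.00765 in Young+YF, 0.00330% ± 0.00833 in Aged+AF and 0.411% ± 0.950 in Aged+YF metagenomes (n = 8 each). The limma difference between the aged groups was 4.54 (adjusted p = 0.106). It was 5.49 (adjusted p = 0.0430) without Aged+AF replicate 4, 4.602 (adjusted p = 0.0263) with centred log-ratios and 4.72 (adjusted p = 0.0346) with median-ratio scaling, and with replicate number as a block its limma adjusted p was 0.0304. Between Aged+AF and Young+YF it passed in limma without the 7 libraries low in Blautia sp.YL58 (-4.53, adjusted p = 0.0129). Klebsiella pneumoniae averaged 0.417% ± 0.802, 0.0116% ± 0.00959 and 0.416% ± 0.804. In 16S, Prevotellaceae UCG 001 was above 0 in 5 of 5 Young+YF and 4 of 5 Aged+YF libraries, at 0.0687% and 0.143%, and listed at 0 in 5 of 5 Aged+AF libraries (limma adjusted p = 0.10002 and 0.118). It passed in limma without Young+YF replicate 1 (adjusted p = 0.0259) or Aged+YF replicate 3 (adjusted p = 0.0244) against Young+YF, and without Aged+YF replicate 3 (adjusted p = 0.00176) against Aged+YF. It also passed in limma with median-ratio scaling against Young+YF (adjusted p = 0.0227), and with a 10th of the added constant against Young+YF (adjusted p = 0.0148) and Aged+YF (adjusted p = 0.0361). Rikenella averaged 0.0275% ± 0.0592 in Young+YF and 1.04% ± 1.92 in Aged+AF (limma adjusted p = 0.10002), and passed in limma without Young+YF replicate 3 (adjusted p = 0.0140) or Aged+YF replicate 2 (adjusted p = 0.0308), or with a 10th of the added constant (adjusted p = 0.0357).

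The 7 metagenome libraries low in Blautia sp.YL58 held 0% to 0.252% of it, against 4.13% to 19.4% in the other 17. Their smallest non-zero value was 0.000177% to 0.000392%, against 4.53e-05% to 0.000103%. The added list of fungi totalled 1.90% ± 1.59 in Young+YF, 2.57% ± 1.98 in Aged+AF and 4.11% ± 2.73 in Aged+YF, and mouse retroviruses 0.0304% ± 0.0254, 0.0360% ± 0.0295 and 0.0626% ± 0.0425, and 0 of these differences passed the two-sided exact permutation tests (lowest adjusted p = 0.0741).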
